A study of Mus musculus with 4 samples.

How the data were processed

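Kidney cells of E14.5 mouse embryos were profiled by Drop-seq in 4 libraries, 2 wildtype and 2 from mutants for 6 Abd-B Hox genes, on a mixed background per the labels. The authors deposited a table of raw counts per gene and cell barcode for each library. Every value was a whole number, and no normalization was found. The submitters' processing notes name Bowtie2 2.2.7 and the genome build mm10. The labels do not state the annotation, the handling of strand or whether molecular identifiers were collapsed; the counts are called UMIs here, and intervals and floors cover counting error only. The tables held 15144 barcodes with at least 500 genes each and 27932 genes in any library.

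Barcodes with at least 500 genes and a mitochondrial share of at most 10% were taken. The 5% of barcodes per library with the highest Scrublet doublet score were left out, 620 in all. Scores served as ranks because automatic thresholds can fail, and the tool's own threshold marked only 22 barcodes. This left 11779 cells. Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes without Hox, Xist, Tsix, chrY, haemoglobin, mitochondrial and ribosomal protein genes. Genes were centred and scaled within each library, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 0) followed. Clusters were named from 16 marker lists. A name needed at least 3 markers among genes with at least 30 counts and a 2-fold lead over the other cells (with 5 CPM added), and stayed "-like". No other list could have more members among the cluster's top 10 genes by fold. Clusters without enough markers, and shallow clusters with no marker in the top 10, stayed unnamed. The progenitor-like class came from clusters 1 and 11 and the stroma-like class from clusters 2, 3, 4, 8 and 13. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

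Cells are not replicates, so counts were summed per library, over all cells and within each class with at least 25 cells in every library, which neural and glial-like and ureter smooth muscle and mural-like cells did not reach. The sums were tested between genotypes with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood test), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are mutant over wildtype. The same test on cell numbers per class, with kept cells as the library size, compared shares, beside an exact two-sided permutation test. Lists were tested with fry, and with camera at a preset correlation of 0.01 and at an estimated correlation (limma 3.58.1); fry's p tests whether a list's genes move, on balance, in 1 direction. For shares of cells with a list's UMIs, each cell was thinned to 1000 UMIs. The genotype effects of progenitor-like and stroma-like cells were compared as an interaction, with library as block, a fit with few residual degrees of freedom. Folds against a group at 0 are lower bounds at a floor of 3 counts over the group. Leaving out a library leaves a genotype with 1 library, which is then assumed to vary like the other genotype.

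The tests, 16 marker lists, 19 gene lists and the rule for named genes were chosen before the data were examined, except where a setting is called added. The rule named the targeted genes; in all cells, progenitor-like and stroma-like cells, the 10 genes with the largest log2 fold change in each direction among those past the test, with a mean of at least 10 CPM and no overlap between genotypes; and 5 in each direction in other classes. It also named up to 4 members of a list past the test, or the 2 with the smallest p, and every gene where 10 or fewer passed. Predicted, haemoglobin, mitochondrial and ribosomal protein genes, Xist and chrY genes were counted, not named, among the largest changes; they are named where 10 or fewer genes passed or as list members. Some results that the rule selects, and a test of an explanation, are not reported here. Of 427 list genes, 3 were in no table (Amh, Hoxd4 and Msmo1). Positions of the named genes came from GENCODE vM21, on the build that the notes name, and were found for 283 of 283 genes.

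Alternatives were DESeq2 1.42.0's size factors and Wald test, no filter on low counts, a replicate block, each library left out, at least 1000 genes per cell, no doublet step, no mitochondrial limit, Leiden resolution 2, centring over all libraries, other thinning depths, and shares without erythroid- and immune-like cells. Added after the data were seen were the clustering without marker genes, the endothelium-like class without its lymphatic cluster, the stromal clusters tested separately, a crossed block, barcodes above 50000 UMIs left out, marker lists over all cells, the other cell filters for shares and marker lists, and, for gene lists, every alternative other than camera.

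The tests were run on simulated counts with the real means and depths and a fixed number of changed genes. Over all cells, 11.9% of genes changed 2-fold, 74.6% of those changed 4-fold and 89.4% of those changed 8-fold were called, and 33 of 161 calls (20.5%) were false. In stroma-like cells the shares were 8.96%, 68.7% and 100%, with 21 of 150 calls (14%) false, and in ureteric bud and collecting duct-like cells 11.9%, 61.2% and 95.5%, with 7.52% false. In progenitor-like cells they were 0%, 34.3% and 78.8%, with 7.87% false, and in early nephron-like cells 8.96%, 59.7% and 93.9%, with 7.75% false. A list of 12 genes raised 4-fold gave fry p values between 0.00066 and 0.0136 where all 12 were tested. An 8-fold change in a class's share was called in 97% of 100 draws, and 11.8% of the other classes were called too. Simulated shares were rescaled to add up to the whole, so the other shares moved as well, and 11.8% is not a rate of false calls alone. Those draws used a fixed dispersion of 0.05, not the spread of the data. The rarest classes, neural and glial-like cells among them, were never the changed class.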

Results

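Single-cell RNA profiles of embryonic mouse kidneys were collected at E14.5 with Drop-seq, in which cells are caught in droplets with barcoded beads and the 3' ends of their transcripts are sequenced. Of the 4 libraries, 2 came from wildtype kidneys and 2 from kidneys labelled as mutant for Hoxa9, Hoxa10, Hoxa11, Hoxd9, Hoxd10 and Hoxd11. These genes belong to the Abd-B class of Hox genes, which pattern the posterior body, and the title of the series concerns how far kidney cells keep to their lineage when that function is reduced. Wildtype 1 held 2113 barcodes and 9817486 counts, and wildtype 2 held 5542 barcodes and 24834658 counts. Mutant 1 held 1061 barcodes and 3572346 counts, and mutant 2 held 6428 barcodes and 21350698 counts. After filtering, 1852, 4788, 810 and 4329 cells were kept, in that order, with median depths of 3585, 3438, 2467 and 3021 counts (UMIs) per cell. A mitochondrial share above 10%, a sign of damaged cells, was found in 8.41% ± 0.917 of wildtype and 24.4% ± 6.72 of mutant barcodes, and these barcodes were left out. Values after ± are SDs over the libraries of a genotype (n = 2). The labels do not say that the libraries came from separate animals, so every p-value measures only the spread between these libraries, which may be technical.

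The targeted genes were read in every library first. Over all kept cells, Hoxa9 gave 129 and 126 CPM (counts scaled to the UMIs of the library, here without TMM) in the wildtype libraries and 136 and 163 in the mutant libraries. Hoxa10 gave 152 and 175 against 91.7 and 127, and Hoxa11 gave 19.7 and 64.0 against 27.9 and 41.6. Hoxd9 gave 27.1 and 39.7 against 51.9 and 47.6, Hoxd10 gave 40.5 and 41.4 against 64.5 and 85.1, and Hoxd11 gave 76.3 and 53.6 against 115 and 196. Hoxa9 lies on chromosome 6 at 52223100 to 52231089 and Hoxd11 on chromosome 2 at 74679557 to 74687016 (mm10). None of the 6 genes passed edgeR's test over all cells. The labels do not say which part of each gene was altered, and a 3' tag outside that part checks nothing, so these levels neither verify nor contradict the genotypes. The antisense transcript Hoxa11os gave 34.2 and 52.6 against 19.4 and 29.1 CPM, and since the labels do not state strand-aware counting, Hoxa11 and Hoxa11os are uncertain.

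**Figure D1:**
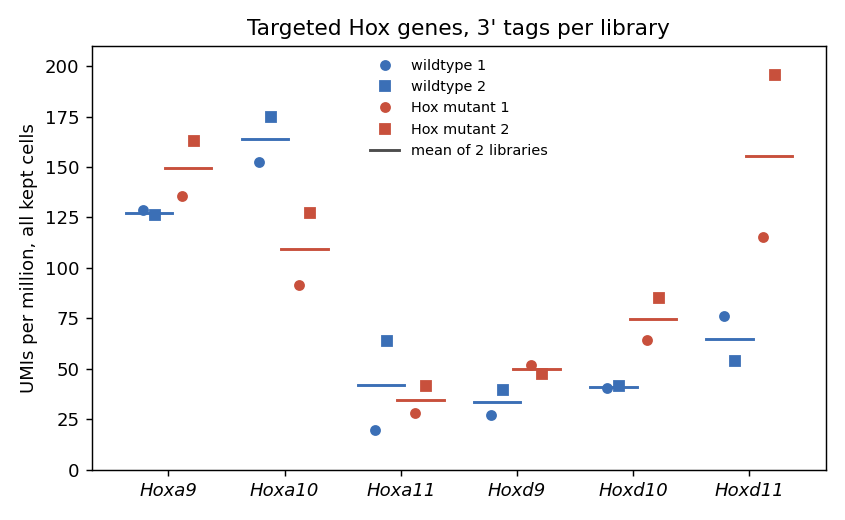
CPM of the 6 targeted Hox genes without TMM over all kept cells (vertical axis), with a point per library and a line at the mean of the 2 libraries of a genotype. Tags of every targeted gene were present in both mutant libraries, between 27.9 and 196 CPM.

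The makeup of the organ was compared first, as the share of kept cells in each class. Nephron progenitor-like cells, the pool that gives rise to nephrons, made up 21.5% ± 0.809 of wildtype and 2.60% ± 0.865 of mutant cells, an 8.26-fold lower share. Neural and glial-like cells made up 0.0209% ± 0.0296 of wildtype and 0.844% ± 0.146 of mutant cells. Their cell numbers were 0, 2, 6 and 41, and 0 of the 1852 cells of wildtype 1 allows a share of up to 0.162%. The top genes of their cluster included Chgb, Chga, Hand2, Dbh and Th, and only Th of these is on the marker list. Whether these cells belong to the kidney itself was not tested. Both differences passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at log2 fold changes of -3.10 (SE 0.40, adjusted p = 0.00553) and 4.71 (SE 0.70, adjusted p = 0.00583). Stroma-like cells made up 23.5% ± 2.83 of wildtype and 41.0% ± 2.42 of mutant cells, and podocyte-like cells, the filtering epithelium of the glomerulus, 3.43% ± 0.569 and 7.78% ± 2.62. Ureteric bud and collecting duct-like cells made up 6.89% ± 1.63 and 3.53% ± 2.87. These 3 classes did not pass (adjusted p = 0.147, 0.109 and 0.438 in edgeR). Early nephron-like cells stood at 5.74% ± 0.354 and 5.94% ± 0.193, loop and distal tubule-like cells at 6.20% ± 0.470 and 6.36% ± 0.443, and proximal tubule-like cells at 4.96% ± 0.696 and 4.60% ± 0.914. The other classes had adjusted p values from 0.747 to 0.894. Shares of a library add up to the whole, so a lower progenitor-like share alone would raise every other share. A higher share therefore does not show more cells of a class, nor a level share an unchanged number. Each class whose libraries did not overlap reached an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give.

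Markers that define the progenitor-like class differ between the genotypes, so its share was also taken from a clustering without any marker gene, a setting added after the data were seen. The log2 fold change was then -3.29 (adjusted p = 0.0118 in edgeR). Centring genes over all libraries gave -5.12 (adjusted p = 0.00117), and over all alternatives the adjusted p lay between 8.88e-06 and 0.0258. Of the 112 mutant cells in the class, 25 stayed progenitor-like under that centring, while 37 became podocyte-like, 27 early nephron-like and 14 stroma-like. Their median was 1.0 UMI of the progenitor list in both mutants, against 8.5 and 8.0 in the wildtype libraries. Over all barcodes, before any filter or clustering, the 12 genes of that list summed to 631 and 625 CPM in the wildtype and 190 and 234 in the mutant libraries. Without mutant 1, the podocyte-like share passed at 1.50 (adjusted p = 0.0173) and the ureteric bud and collecting duct-like share at -2.19 (adjusted p = 0.00479). With erythroid- and immune-like cells outside the total, the stroma-like share passed at 0.76 (adjusted p = 0.0449).

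**Figure D2:**
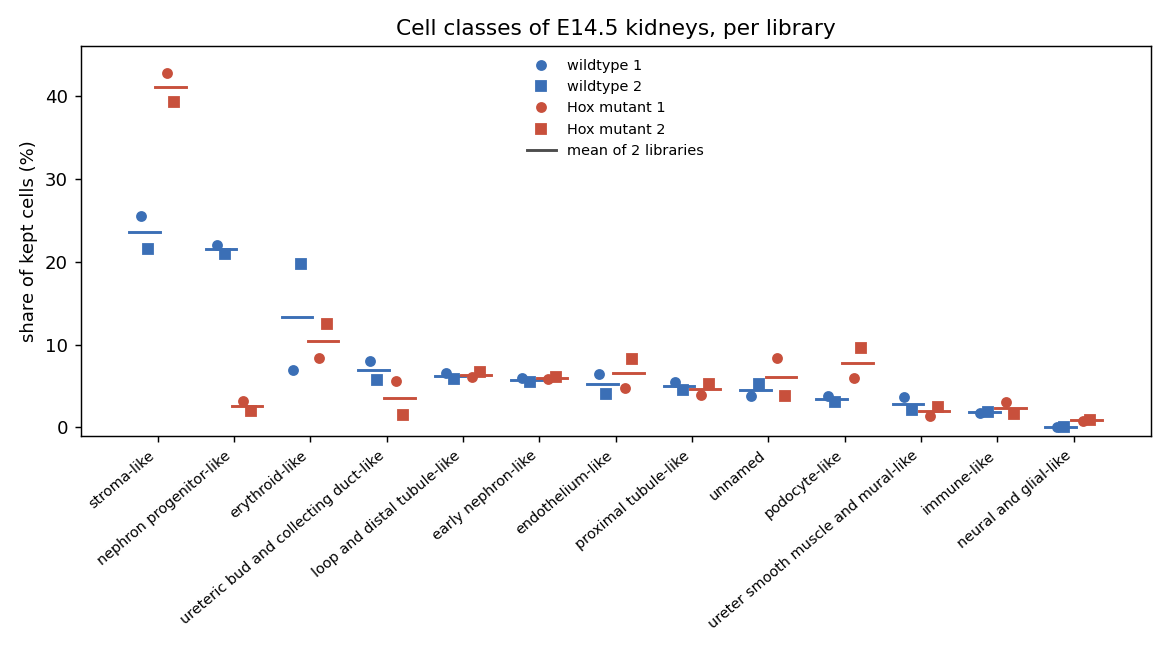
Share of kept cells (percent, vertical axis) in each class (horizontal axis), with a point per library and a line at the mean of the 2 libraries of a genotype. Nephron progenitor-like cells average 21.5% in wildtype and 2.60% in mutant libraries.

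Several genes of nephron progenitors were lower over the whole organ. Cited1, a transcriptional co-regulator of uninduced progenitors (chromosome X, 102247381 to 102252181), averaged 133 ± 34.0 CPM (with TMM, as for all single genes from here) in wildtype and 9.54 ± 2.54 in mutant libraries, a log2 fold change of -3.85 (SE 0.39, adjusted p = 1.97e-06). Six2, the homeobox factor that maintains the pool (chromosome 17, 85684277 to 85688274), fell from 26.8 ± 0.936 to 3.23 ± 1.84 CPM (-3.25, SE 0.45, adjusted p = 0.000189). Eya1, its cofactor, fell from 36.4 ± 1.61 to 5.44 ± 1.28 CPM, and Crym, a thyroid hormone-binding protein, from 91.8 ± 31.7 to 7.02 ± 2.15. The homeobox gene Meox2 (-3.37) and the proteoglycan gene Spock2 (-3.04) fell as well. Of 15 measured regulators of nephron progenitors, 6 passed and 10 were lower when adjusted over the list alone, with 14 below 0. The fry p of that list was 0.0121, or 0.114 after adjustment over 19 lists, and p = 0.0162 (adjusted p = 0.153) with an estimated correlation. The marker list of the same cells, tested over all cells as an addition made after the data were seen, was lower at an adjusted fry p of 0.0154, a call that is lost with an estimated correlation (adjusted p = 0.0853).

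The ureteric bud branches in response to GDNF, which signals through the receptor Ret and its co-receptor Gfra1 to the ETS factors Etv4 and Etv5. All 12 measured members of that list had log2 fold changes below 0, and 4 passed, or 10 when adjusted over the list alone. Etv4 (chromosome 11, 101769742 to 101785371) fell from 45.9 ± 11.6 to 8.91 ± 1.61 CPM, a log2 fold change of -2.34 (SE 0.39, adjusted p = 0.00143), and Etv5 (chromosome 16, 22381309 to 22439719) from 41.6 ± 4.92 to 8.56 ± 2.94. Ret averaged 10.7 ± 2.25 and 2.24 ± 0.959 CPM (adjusted p = 0.00707) and Gfra1 65.7 ± 17.8 and 21.9 ± 7.59 (adjusted p = 0.0301). The list's fry p was 0.00514, or 0.0977 adjusted over 19 lists, with p = 0.0135 (adjusted p = 0.153) under an estimated correlation. Outside the lists of progenitor and branching genes, the keratin gene Krt23 (-3.47), the calcium-binding protein gene S100g (-3.13) and Elavl4, an RNA-binding protein (-2.63), fell. Elavl4 was among the top 10 genes by fold of progenitor-like cluster 11, so its fall is not separate from the lower progenitor-like share. Col2a1, the collagen of cartilage, was lower at -1.70 (adjusted p = 0.0309). Ret lost its call without mutant 2 (adjusted p = 0.0831), Gfra1 without wildtype 1 (0.106) or mutant 1 (0.193), and Col2a1 without wildtype 2 (0.251) or mutant 1 (0.0981). Without the mitochondrial limit, Gfra1 (0.0844) and Col2a1 (0.122) lost theirs as well, and Gfra1 also without barcodes over 50000 UMIs (0.0514).

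Genes that were higher included members of the matrix and neural lists. Postn, a matricellular protein, rose from 48.5 ± 22.8 to 340 ± 12.6 CPM, a log2 fold change of 2.82 (SE 0.37, adjusted p = 0.000108). The proteoglycans Lum and Dcn rose from 36.1 ± 2.84 to 176 ± 11.2 and from 110 ± 29.9 to 493 ± 130 CPM. Col6a1 (2.08), Col6a2 (2.11), the fibroblast protease gene Fap (2.68), the chemokine gene Cxcl13 (2.66) and the transcription factor gene Gata6 (2.46) rose too. Of 18 matrix genes, 8 passed and 12 were higher when adjusted over the list alone; its fry p was 0.0446, or 0.282 adjusted, with p = 0.0644 under an estimated correlation. Chga and Chgb, granins of neuroendocrine secretory granules, rose from 0.483 ± 0.375 to 27.5 ± 7.72 and from 2.07 ± 1.38 to 115 ± 38.2 CPM. Th, the enzyme that starts catecholamine synthesis, rose at 3.62, and the neurofilament gene Nefm rose from 9.56 ± 0.192 to 124 ± 67.5 CPM. The list of neural and glial markers was higher at an adjusted fry p of 0.0154, a call that is lost with an estimated correlation (adjusted p = 0.254), and its member Elavl4 went the other way. Ccl21a, a lymphatic chemokine, rose from 0.767 ± 0.467 to 73.5 ± 25.7 CPM. Meg3 and Dlk1, of the same imprinted locus, rose from 173 ± 54.5 to 880 ± 333 and from 97.0 ± 14.6 to 351 ± 59.6 CPM. Plac9a (2.43) and Plac9b (2.41) are near-identical copies, as are the Ccl21 genes, and their split is uncertain. The mesothelial gene Upk3b was higher at 2.99 (adjusted p = 0.0396).

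Over all cells, edgeR called 173 of 15770 genes, 127 higher and 46 lower in the mutants. These totals mix changes in cell shares with changes within cells. The count was 326 without wildtype 1, 256 without wildtype 2, 334 without mutant 1 and 403 without mutant 2, with 144, 113, 155 and 135 of the 173 genes called each time. Upk3b lost its call without wildtype 1 (adjusted p = 0.148), wildtype 2 (0.0942) or mutant 1 (0.0645), with DESeq2 (0.0546), with at least 1000 genes (0.0902) and without the mitochondrial limit (0.0657).

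**Figure D3:**
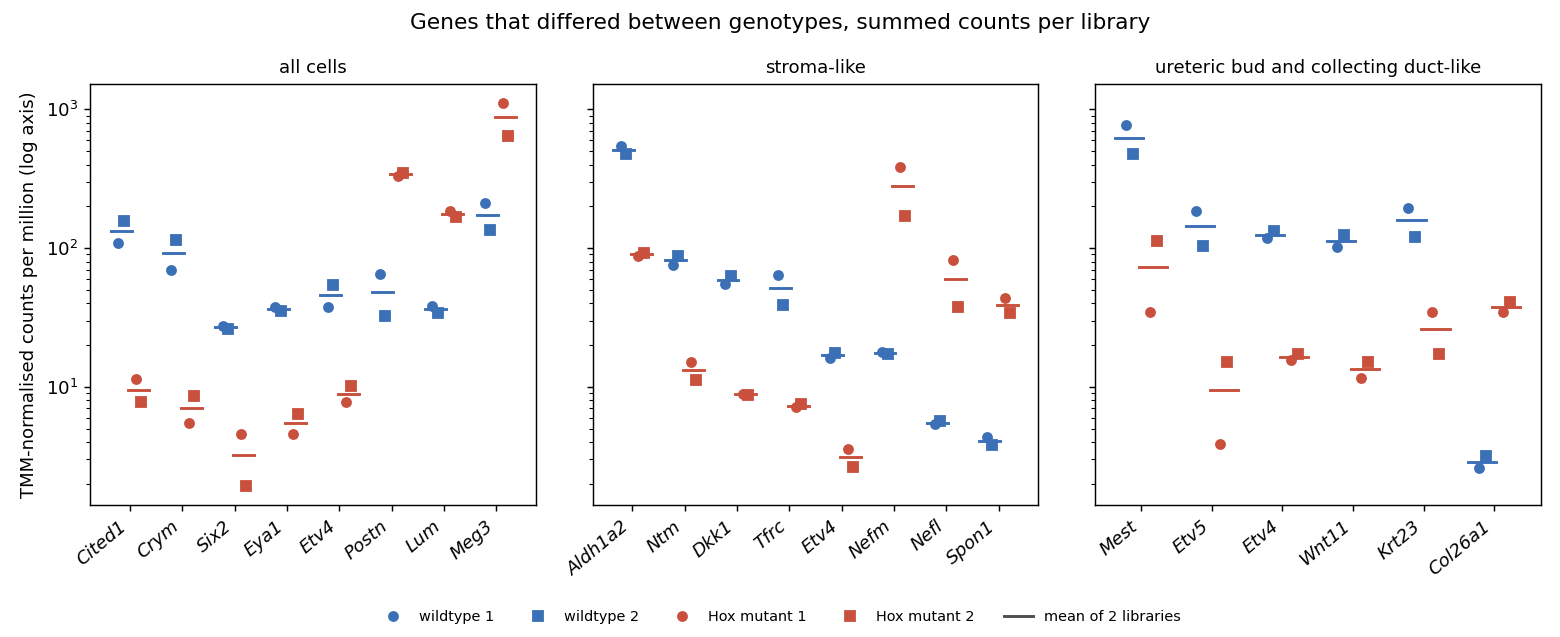
TMM-normalised CPM on a log axis (vertical) for named genes (horizontal) in sums over all cells, stroma-like cells and ureteric bud and collecting duct-like cells, with a point per library and a line at the mean of the 2 libraries of a genotype. Every gene shown has both mutant libraries on the same side of both wildtype libraries.

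Of the other lists over all cells, none passed fry after adjustment over 19 lists. The adjusted p was 0.305 for hypoxia and glycolysis and for S phase genes and 0.327 for G2 and M phase genes, each lower, and 0.305 for imprinted growth genes, which were higher with 2 of 12 past the test (Meg3 and Dlk1). It was 0.539 for Wnt and beta-catenin targets, 0.556 for BMP and TGF-beta targets, 0.787 for the targeted Hox genes, and 0.890 for immediate early genes and for retinoic acid genes. It was 0.900 for sex genes, Hox paralogs 1 to 8, the Notch pathway, p53 targets, heat shock genes, other Abd-B Hox genes and cholesterol synthesis. For retinoic acid genes, fry pointed lower while the median log2 fold change was 0.01, and for other Abd-B Hox genes fry and the mean (-0.04) pointed lower while the median was 0.23. Among marker lists over all cells, the adjusted p of fry was 0.0850 for cartilage and bone (lower; Col2a1 passed) and 0.159 for stroma (higher; 8 of 23 passed), with p = 0.0437 and 0.0662 under an estimated correlation. It was 0.343 for podocytes, mesothelium and proximal tubule, 0.388 for ureter smooth muscle, early nephron and ureteric bud, 0.448 for endothelium and 0.464 for immune cells. It was 0.747 for skeletal muscle, 0.885 for erythroid cells and 0.918 for loop and distal tubule, whose median (-0.18) and mean (0.02) differed in sign.

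Within stroma-like cells, the question was which genes differ when cell shares are set aside. Aldh1a2, which makes retinoic acid (chromosome 9, 71215789 to 71296243), fell from 509 ± 47.2 to 90.1 ± 3.18 CPM, a log2 fold change of -2.50 (SE 0.37, adjusted p = 0.00522). Dkk1, a secreted Wnt antagonist, fell from 59.2 ± 5.79 to 8.81 ± 0.0884 CPM, and Ntm, a neural adhesion molecule, from 81.5 ± 8.23 to 13.2 ± 2.71. The transferrin receptor gene Tfrc fell from 51.4 ± 17.5 to 7.30 ± 0.283 CPM and the interferon-inducible GTPase gene Iigp1 from 28.1 ± 0.759 to 2.72 ± 0.0813. Cited1 fell by 4.99 on the log2 scale, from 31.2 ± 8.21 to 0.930 ± 0.0601 CPM. The factors Uncx (-2.90), Pax2 (-2.76) and Etv4 (-2.55) and Spock2 (-2.63) were lower. Of 11 progenitor regulators measured here, 3 passed, or 8 adjusted over the list alone (fry p = 0.0347, or p = 0.0352 with an estimated correlation). After adjustment over the lists of the class, that list passed neither test.

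Nefm and Nefl, subunits of neurofilaments, rose in stroma-like cells from 17.5 ± 0.518 to 278 ± 152 and from 5.51 ± 0.150 to 59.7 ± 31.0 CPM, and Nefm lies on chromosome 14 at 68082590 to 68124846. The matrix gene Spon1 rose from 4.08 ± 0.349 to 38.9 ± 6.49 CPM, and Lum from 117 ± 22.9 to 421 ± 58.0. Ntrk3, a neurotrophin receptor (3.07), Rgs7bp (2.62), Lonrf1 (2.55), the monooxygenase gene Fmo2 (2.49), the protease gene Adamts18 (2.41), the protocadherin gene Pcdh7 (2.40), the ectoenzyme gene Cd38 (2.39) and the sialomucin gene Emcn (1.86) were higher as well. EdgeR called 45 of 11596 genes, 27 higher and 18 lower. The count was 226 without wildtype 1, 165 without wildtype 2 and 147 without mutant 1, with 45, 32 and 44 of the 45 called each time. Without mutant 2 it was 56, with only 20 of the 45, and with likely doublets kept it was 142. Of the 22 genes named in this class, 6 lost their call without wildtype 2, namely Pax2 (adjusted p = 0.196), Uncx (0.140), Lum (0.0920), Pcdh7 (0.0920), Ntrk3 (0.0676) and Emcn (0.0540). Without mutant 2, Spock2 (0.467), Ntrk3 (0.281), Etv4 (0.261), Pcdh7 (0.256), Emcn (0.136), Pax2 (0.130), Fmo2 (0.0674) and Adamts18 (0.0593) lost it. Pax2 (0.110) and Uncx (0.111) lost it without the mitochondrial limit, Pax2 (0.0531), Ntrk3 (0.0624) and Uncx with at least 1000 genes, and Pax2 with centring over all libraries (0.117). Malat1, abundant in damaged cells and looked at after its values were seen, had a log2 fold change above 0 in every class, and of 1.26 in this one (adjusted p = 0.496), at 2740 and 2004 CPM without TMM against 4551 and 6829, so a difference in RNA quality is not excluded.

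In the nephron progenitor-like class, most mutant cells changed class with the centring, so its comparison sets wildtype progenitors against a mixed group. Cited1 fell from 413 ± 44.8 to 6.68 ± 9.44 CPM (log2 fold change -5.32, SE 0.59, adjusted p = 0.000335), and Meox2 (-5.54), Pla2g7 (-4.44), Spock2 (-2.82), the tropomyosin gene Tpm2 (-2.77), Ramp2 (-2.56) and Ttc28 (-2.16) fell too. Of the marker lists of other lineages, 1 early nephron, 1 podocyte and 4 stroma genes were higher past the test, and none of these lists passed fry (adjusted p = 0.221, 0.359 and 0.236). Higher genes named here were Lhx1, a factor of induced nephrons (2.25), Irx3, of nephron tubules (4.72), Podxl, the podocyte sialomucin (3.52), Wnt5a (3.65), Wnt16 (4.35), Col1a2 (3.69), Timp3 (3.70), Dlk1 (3.70) and Npr3 (3.56), with Cryab (4.54), Sbspon (3.99) and Map2 (3.78). EdgeR called 37 of 9633 genes, 30 higher and 7 lower, and the count was 56 without wildtype 2, 136 without mutant 1 and 148 without mutant 2. Of the 19 genes named here, 8 kept their call whichever library was left out: 10 lost it without wildtype 1, 7 without wildtype 2, 2 without mutant 1 and 5 without mutant 2. Podxl lost it in each case (lowest adjusted p 0.0709). At resolution 2, Lhx1 (0.0588), Wnt5a (0.0564) and Npr3 lost theirs.

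In ureteric bud and collecting duct-like cells, the Ret targets Etv4, Etv5 and Wnt11 were lower. Etv5 fell from 145 ± 57.7 to 9.47 ± 7.92 CPM, a log2 fold change of -3.73 (SE 0.57, adjusted p = 0.0170), and Etv4 from 125 ± 10.6 to 16.3 ± 1.23. Wnt11, a signal of the bud tip (chromosome 7, 98835112 to 98855195), fell from 113 ± 15.2 to 13.3 ± 2.44 CPM. The imprinted gene Mest fell from 627 ± 211 to 73.4 ± 54.5 CPM and Krt23 from 158 ± 52.9 to 26.0 ± 12.4. The calcium sensor gene Vsnl1 had 121 UMIs in the wildtype and 0 in the mutant libraries, at least 8.25-fold lower at a floor of 3 counts over the group. The collagen gene Col26a1 rose from 2.87 ± 0.404 to 37.9 ± 4.29 CPM. Of the 11 GDNF and RET genes measured here, 3 passed, or 9 adjusted over the list alone (fry p = 0.0250, and p = 0.0108 with an estimated correlation). The list passed neither test after adjustment over the lists of the class. Among S phase genes, Mcm3 stood at -1.67 (adjusted p = 0.246) and Ung at -1.78 (adjusted p = 0.322), and neither passed. EdgeR called 7 of 8748 genes, and left-out libraries gave 47 (wildtype 1), 118 (wildtype 2), 24 (mutant 1) and 40 (mutant 2). Vsnl1 lost its call without wildtype 1 (adjusted p = 0.127), and Krt23 (0.141) and Col26a1 (0.158) without mutant 2. Krt23 also lost it with at least 1000 genes (0.0596) and with clustering without marker genes (0.0557), and Vsnl1 with DESeq2 (0.0916) and at least 1000 genes (0.0502). Malat1 had its largest log2 fold change of any class here (1.85, adjusted p = 0.0825), at 2620 and 2084 CPM without TMM against 7973 and 9464, so a difference in RNA quality is not excluded. Clustering without marker genes gave a cluster led by Calb1, with Ret and Krt23, of 140 and 238 wildtype and 29 and 50 mutant cells. A second, led by Fxyd4, held 13 and 39 against 13 and 17. Whether this mix within the class lowered Etv4, Etv5, Wnt11 or Krt23 was not tested.

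In loop and distal tubule-like cells, the genes of the calcium-binding proteins S100g and Calb1 were among those that were lower. Calb1 is on the ureteric bud marker list and led the ureteric bud cluster. Whether ureteric RNA or cells within this class account for the fall of Calb1 was not tested. S100g fell from 151 ± 65.3 to 10.2 ± 1.61 CPM (log2 fold change -3.80, SE 0.49, adjusted p = 0.00167). The calcium-binding protein gene Calb1 fell from 47.9 ± 18.5 to 1.78 ± 2.52 CPM, the growth factor gene Bmp2 from 88.1 ± 6.18 to 15.4 ± 2.62, and the tetraspanin gene Tspan8 from 136 ± 39.1 to 25.4 ± 10.4. Of the targeted genes, Hoxd11 rose here from 79.9 ± 17.2 to 361 ± 102 CPM (adjusted p = 0.0341). The related Hoxc9 stood at 22.1 ± 19.4 and 109 ± 11.9 CPM (adjusted p = 0.281) and Hoxc10 at 45.7 ± 11.4 and 155 ± 36.4 (adjusted p = 0.217), and neither passed. These 5 calls came from 9321 genes. Without mutant 2, 3 genes were called, none of the 5 among them (Calb1 0.178, S100g 0.102, Bmp2 0.304, Tspan8 0.177, Hoxd11 0.165). The log2 fold changes of S100g (-4.05), Bmp2 (-2.68), Tspan8 (-2.91) and Hoxd11 (1.88) stayed large there, and Calb1 had 0 UMIs in mutant 1, so the lost calls do not show that mutant 2 carries the changes. Without wildtype 1, wildtype 2 and mutant 1 there were 31, 29 and 8; Calb1 (0.0821) and Hoxd11 (0.0665) lost their call without wildtype 2, and Bmp2 (0.0998) and Tspan8 (0.216) without mutant 1. S100g lost its call in no other setting. The other genes of the 5 lost theirs with likely doublets kept (adjusted p from 0.112 to 0.186) and with clustering without marker genes (from 0.148 to 0.296), Bmp2, Calb1 and Tspan8 with DESeq2 (from 0.0841 to 0.112), Bmp2 (0.681), Tspan8 (0.168) and Hoxd11 (0.0845) at resolution 2, Bmp2 with centring over all libraries (0.0668), and Tspan8 with at least 1000 genes (0.0758) or without the mitochondrial limit (0.0638).

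In endothelium-like cells, Ccl21 genes and Prox1 were among those that differed. Ccl21a had 0 UMIs in the wildtype and 1225 in the mutant libraries, at least 286-fold higher, and Ccl21b had 0 and 215, at least 50.3-fold higher, at a floor of 3 counts over the group. Prox1, the factor that specifies lymphatic endothelium, rose from 2.87 ± 1.86 to 54.4 ± 11.5 CPM (SE 0.65 on the log2 scale, adjusted p = 0.00187). B3gnt2 (5.05) and Tsix (3.97) were higher. Tsix overlaps Xist on the other strand, and Xist over all cells ran from 0.654 CPM in wildtype 1 to 158, 571 and 249 in wildtype 2, mutant 1 and mutant 2, so a difference in sex between libraries is not excluded as its source. EdgeR called 11 of 8062 genes, and 0 once the lymphatic cluster of 25 cells was left out (added after the data were seen). That cluster held 1 cell of mutant 1 and 24 of mutant 2, so the Ccl21 and Prox1 values of mutant 1 may rest on 1 cell. B3gnt2 (5.07, adjusted p = 0.279) and Tsix (3.76, adjusted p = 0.0825) kept their size without it, so the loss of their calls does not tie them to that cluster, and Ccl21a, Ccl21b and Prox1 gave no value there. Without the cluster, 339 genes had an unadjusted p under 0.05, and with it DESeq2 called 7. Prox1 lost its call without mutant 2 (adjusted p = 0.0520) and B3gnt2 without wildtype 2 (0.353), with DESeq2 (0.624), with at least 1000 genes (0.0863) and without the mitochondrial limit (0.0547). With likely doublets kept, Ccl21a and Ccl21b lost theirs (adjusted p = 1.0 for Ccl21a and 0.165 for Ccl21b), while 23, 21 and 64 genes were called without wildtype 2, mutant 1 and mutant 2.

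The erythroid-like class held mixed barcodes. Thinning leaves out cells under 1000 UMIs, and the median depth of the class was 952 UMIs, so the shares given here cover only its deeper cells. Erythroid UMIs were held by 10.0% and 73.6% of these cells in the wildtype and 9.30% and 66.9% in the mutant libraries. Stroma UMIs were held by 54.3% and 41.2% against 62.8% and 83.1%. A rise in the class need not come from erythroid cells. In this class, 10 of 5215 genes rose, and 6 of 18 stromal markers were among them (fry p = 0.0327, and p = 0.0293 with an estimated correlation). That list did not pass after adjustment (adjusted fry p = 0.221, and adjusted p = 0.417 with an estimated correlation). Postn rose from 8.21 ± 4.21 to 208 ± 40.3 CPM (log2 fold change 5.02, SE 0.57, adjusted p = 0.000292), and Lum (4.15), Meg3 (3.84), Dcn (3.59), Apoe (3.43), Col6a2 (3.30), Sfrp1 (2.90), Col1a2 (2.71), Col1a1 (2.40) and Dlk1 (2.19) rose too. With genes centred over all libraries, 2 genes passed. Left-out libraries gave 31 (wildtype 1), 27 (wildtype 2), 26 (mutant 1) and 37 (mutant 2): Col1a1 was lost without wildtype 1 (adjusted p = 0.0649), Col1a2 (0.230), Col6a2 (0.375) and Dlk1 (0.131) without wildtype 2, and Apoe (0.519) and Dlk1 (0.387) without mutant 2. With DESeq2's size factors Col1a2 (0.0663), Col6a2 (0.0699) and Dlk1 (0.0786) were lost, with its Wald test Col6a2 (0.609) and Dlk1 (0.151), without the mitochondrial limit Col1a2 (0.110), and at resolution 2 Apoe (0.0578). In immune-like cells, the neutrophil gene S100a9 had 46 UMIs in the wildtype and 0 in the mutant libraries, at least 11.7-fold lower, and mt-Atp8 was higher at 2.96 (adjusted p = 0.0434). These were the 2 calls of 2846 genes, where DESeq2 called 0, and 22, 16, 13 and 16 genes were called without wildtype 1, wildtype 2, mutant 1 and mutant 2. S100a9 lost its call without mutant 2 (adjusted p = 0.0874) and with centring over all libraries (0.0714), and both genes lost theirs with clustering without marker genes (0.0642).

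The title of the series raises the question whether cells of 1 lineage carry RNA of another, and marker lists were tested in every class other than their own. None of the 62 combinations passed fry after adjustment (11 had an unadjusted p under 0.05, and the lowest adjusted p was 0.149), camera with a preset correlation passed 13, and with an estimated correlation 0. In the simulated counts, 12 genes raised 4-fold gave fry p values from 0.00066 to 0.0136. Adjustment over 62 tests can lift such values past the threshold, and most lists here had fewer genes. A missing call therefore does not show an unchanged list. In early nephron-like cells, the podocyte list stood higher, with a fry p of 0.00719 and p = 0.0470 with an estimated correlation. It pointed higher in all 8 classes where it was tested, with smaller fry p values in proximal tubule-like (0.00292, and p = 0.172 with an estimated correlation) and erythroid-like cells (0.00598, and p = 0.134 with an estimated correlation). Of its 8 genes in early nephron-like cells, 0 passed over all genes and 4 were higher when adjusted over the list alone, Podxl among them. Podxl averaged 3.58 ± 2.10 CPM in wildtype and 21.7 ± 3.56 in mutant early nephron-like cells (adjusted p = 0.370). The progenitor genes Cited1 (-1.95) and Osr1 (-3.39) and the Abd-B gene Hoxc11 (2.13) did not pass there either (adjusted p = 0.727, 0.727 and 0.447). The progenitor list in stroma-like cells gave a fry p of 0.0349, lower, with 2 of 11 genes past the test, and 6 lower and 1 higher adjusted over the list alone (p = 0.0313 with an estimated correlation). The early nephron list in loop and distal tubule-like cells gave p = 0.0112, lower, with Bmp2 past the test (p = 0.0457 with an estimated correlation). EdgeR called 0 genes in early nephron-, podocyte- and proximal tubule-like cells, where 376, 270 and 289 genes had an unadjusted p under 0.05 and DESeq2 also called 0. Left-out libraries gave 14 to 72, 6 to 33 and 4 to 18 genes in these classes, and the highest counts came without mutant 2, wildtype 1 and mutant 2.

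The same question was put to single cells, each thinned to 1000 UMIs, as the share with at least 2 UMIs of a list. In early nephron-like cells, 22.9% ± 4.93 of wildtype and 29.0% ± 1.07 of mutant cells held podocyte UMIs, with unthinned shares of 81.1% and 89.7% against 89.4% and 85.6%. In ureteric bud and collecting duct-like cells, a class of another lineage, the share was 15.8% ± 1.85 and 31.2% ± 5.28. Median depths were 6898 and 7948 (wildtype) and 6942 and 6853 UMIs (mutant) in the former class, and 4697 and 5253 against 5229 and 5220 in the latter. The podocyte list holds Cdkn1c and Sparc, which many cells express. In loop and distal tubule-like cells it was found in 8.26% ± 3.07 and 20.4% ± 1.24. Progenitor UMIs were held by 4.21% ± 2.08 and 3.34% ± 1.97 of stroma-like cells and 3.07% ± 0.491 and 2.29% ± 3.24 of early nephron-like cells. Erythroid UMIs, which mark free RNA, were held by 8.94% ± 12.6 and 3.95% ± 2.51 of early nephron-like cells and immune UMIs by 0% and 0.191%. Of 150 pairs of class and list, 35 had no overlap between genotypes, 20 higher and 15 lower in the mutants. Many pairs lay at or near 0% and could not separate. Of the 56 pairs with a share of at least 5% in a library, 14 were higher and 8 lower without overlap, where chance gives 33.3% of untied pairs, and pairs of the same libraries are not independent. Cells under 1000 UMIs, 152 and 719 in the wildtype and 121 and 712 in the mutant libraries, were left out.

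Gene lists were also tested within classes, and 0 of 185 tests passed fry after adjustment within a class (21 had an unadjusted p under 0.05). Camera passed 66 with a preset correlation and 0 with an estimated correlation. As with the marker lists, a missing call does not show an unchanged list. The lowest adjusted p was 0.0602, for Notch genes in endothelium-like cells, higher in the mutants (unadjusted p = 0.176 with an estimated correlation). Other Abd-B Hox genes pointed higher in loop and distal tubule-like cells (adjusted fry p = 0.147, or adjusted p = 0.303 with an estimated correlation) and in early nephron-like cells (adjusted fry p = 0.615, or adjusted p = 0.483), and passed in neither.

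Last, the genotype effect in nephron progenitor-like cells was compared with that in stroma-like cells as an interaction within libraries. In edgeR it differed for 275 of 11671 genes, 183 with the larger log2 fold change in progenitor-like cells and 92 with the larger in stroma-like cells. Aldh1a2, which fell in stroma-like cells, Tpm2, which fell in progenitor-like cells, and Timp3, which rose there, were among them. So were haemoglobin genes such as Hbb-y (adjusted p = 1.4e-16 in edgeR) and Xist (adjusted p = 2.1e-07). Haemoglobin marks free RNA here, and Xist differed between libraries of a genotype. A call therefore need not be an effect of genotype within these cells. The count was 42 without wildtype 1, 46 without wildtype 2, 405 without mutant 1 (210 and 195 in the same order) and 154 without mutant 2 (87 and 67). Without the filter on low counts the balance turned, to 131 and 154, so it depends on the processing.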

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

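The tests of explanations below, and the choice of the stromal clusters tested separately, were made only after the results were seen; the interaction was chosen before.

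The genotype effect was called different between progenitor-like and stroma-like cells for 275 genes, by a test of the difference itself. Haemoglobin genes and Xist were among them, so the count does not measure class-specific effects of genotype alone. The count was 42 and 46 without a wildtype library and 405 without mutant 1, and only 25 of the 112 mutant cells in the progenitor-like class stayed in it under the other centring, so unlike cells may be compared here. Among mutant barcodes, 24.4% on average exceeded the mitochondrial limit, against 8.41% of wildtype barcodes, and these barcodes were outside the comparisons. The cluster led by lymphatic genes held 25 mutant cells (1 and 24) and 0 wildtype cells. The neural and glial-like class, too small for a test of its genes, held 47 mutant cells (6 and 41) and 2 wildtype cells, led by Chgb, Chga, Hand2, Dbh and Th, genes of sympathetic and chromaffin cells.

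Genes that changed in stroma-like cells. RNA of the progenitors outside their own cells would fall with them. Six2, the marker that leaves the least room, allows a share of progenitor RNA of at most 10.8% in wildtype stroma-like cells. That share accounts for at most 45.1% of the loss of any of the 14 lower genes outside the progenitor lists (median 3.91%). This argues against progenitor RNA as the main source of these losses. It could still supply a sizeable part for Etv4 (45.1%), Pla2g7 (29.6%) and Tfrc (24.9%). RNA of other classes was not bounded, and Etv4 also fell in ureteric bud and collecting duct-like cells. For Cited1, Pax2, Uncx and Spock2, the lower genes in those lists, the share of progenitor RNA leaves room for the whole loss (at least 115%). Free RNA would bring them to other classes as well, but their sum reached only 22.3% and 24.4% of its wildtype stroma-like level in endothelium- and immune-like cells, against 165% in the mixed erythroid-like class, so this source and a change within the stroma cannot be told apart. In 5 of 5 stromal clusters the called genes that could be tested kept between 65.0% and 118% of their median change in the class. That argues against a shift between the clusters as drawn. Genes were centred within each library, which can place unlike stromal cells together, so a shift between stromal states is not decided. With centring over all libraries, a stromal cluster led by Akr1b7, Fibin and Aldh1a2 held 205 and 399 wildtype and 30 and 66 mutant cells. Another, with Lum, Postn and Nefm, held 45 and 26 against 96 and 577. A lower level of Aldh1a2, Dkk1 and Ntm within stromal cells of the mutants may be an effect of genotype. That hypothesis stays open beside a shift between stromal states and differences between libraries, such as in RNA quality.

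Podocyte genes in early nephron-like cells. Free podocyte RNA in every droplet would raise these genes in all classes alike. Without Cdkn1c, endothelium-, loop and distal tubule-, proximal tubule- and ureteric bud-like cells gained 0.762%, 16.9%, 41.2% and 2.46% of what early nephron-like cells gained (median 9.68%), but that gain, 139 CPM, had an SE of 63.8, so this source cannot be told apart. For Cdkn1c the same classes gained 87.4%, 87.1%, 66.2% and 18.2% (median 76.7%), which cannot be told apart either, since ureteric bud-like cells lay far below the others. Further classes went both ways. Without Cdkn1c, erythroid-, progenitor- and immune-like cells gained 87.4%, 54.6% and 17.6% of the gain in early nephron-like cells, and stroma-like cells stood at -90.4%. More precursors on the way to podocytes may also explain the gain, a hypothesis that was not tested, and no single gene passed edgeR's test over all genes.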

How the results depend on the processing

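The settings called added, and the crossed block, were chosen after the data were seen; the others were chosen before. The 111 results for named genes kept their direction in all 1415 values under other settings, but nearly all had no overlap between genotypes, most by the rule that named them, so leaving out a library could not turn them. Of these values, 1265 kept their side of the threshold, 132 lost the call and 18 gained it; 61 of 102 called genes kept their call whichever library was left out, and 55 under every setting that gave a value. DESeq2 gave no adjusted p for 3. The progenitor-like and neural and glial-like shares passed under every setting, with log2 fold changes from -5.12 to -2.74 and from 4.10 to 4.85; without wildtype 2, no fold is given for the latter, as wildtype 1 held 0 of these cells. Shares that passed elsewhere were the stroma-like share without erythroid and immune classes (0.76), and without mutant 1 the podocyte-like (0.80 to 1.50 over left-out libraries) and ureteric bud-like share (-2.19 to -0.30). The cause was not tested for any change below, except that a left-out library or another filter alters which genes are tested.

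Counts of called genes moved as follows. Without the filter on low counts they were 26 (early nephron), 19 (erythroid), 9 (immune), 19 (loop and distal tubule), 105 (progenitor), 6 (podocyte), 3 (proximal tubule), 162 (stroma) and 56 (ureteric bud). With DESeq2's test they were 7 (endothelium), 0 (immune), 2 (loop and distal tubule), 75 (stroma) and 12 (ureteric bud). Without the doublet step they were 6 (early nephron), 16 (erythroid), 1 (loop and distal tubule), 82 (progenitor), 3 (podocyte), 142 (stroma) and 28 (ureteric bud). Without the mitochondrial limit there were 18 (early nephron) and 31 (ureteric bud). Centring over all libraries gave 2 (erythroid) and resolution 2 gave 2 (loop and distal tubule). Clustering without marker genes, added, gave 1 (early nephron), 0 (immune), 1 (loop and distal tubule) and 71 (progenitor), and the endothelium without its lymphatic cluster, added, gave 0.

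Left-out libraries gave 256 to 403 genes over all cells (326 and 334 in between), 14 to 72 in early nephron, 15 to 64 in endothelium (21 and 23 in between), 26 to 37 in erythroid, 13 to 22 in immune, 3 to 31 in loop and distal tubule, 45 to 148 in progenitor (56 in between), 6 to 33 in podocyte, 4 to 18 in proximal tubule, 56 to 226 in stroma (147 in between) and 24 to 118 in ureteric bud. For the interaction they gave 42 to 405 (154 in between).

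The labels link same-numbered libraries only by the number. Some features went with it. Unnamed cluster 20 held 25 cells of wildtype 1 and 39 of mutant 1, and 0 of either other library. The erythroid list over all cells summed to 206 CPM in wildtype 1 and 604 in mutant 1, against 18280 in wildtype 2 and 3040 in mutant 2. A batch shared by number is therefore not excluded. The deviations of same-numbered libraries correlated at 0.0762 over all cells and between -0.159 and -0.0177 in the classes. A replicate block gave 353 genes over all cells, 1 in early nephron, 30 in erythroid, 11 in immune, 3 in loop and distal tubule, 94 in progenitor, 2 in podocyte, 4 in proximal tubule, 92 in stroma and 42 in ureteric bud, 3 marker lists and 1 gene list, and ended the calls of Bmp2, Tspan8 and Hoxd11 in loop and distal tubule and of B3gnt2 in endothelium. Crossing the pairing, added where the correlation was under -0.1, gave 54 genes in ureteric bud and 0 in early nephron, podocyte and proximal tubule.

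For marker lists, DESeq2's size factors passed 1 and camera with a preset correlation 13, where fry passed 0. For gene lists within classes, camera was set beside fry before the data were seen and passed 66 with a preset correlation; the other alternatives were added: size factors passed 1, at least 1000 genes 1, clustering without marker genes 2, no doublet step 1, no mitochondrial limit 2, and left-out libraries 0 to 3. The thinned comparison gave 35 pairs without overlap between genotypes, and 26 to 35 under its alternatives. The genes of the progenitor-like class could not be tested with centring over all libraries, with at least 1000 genes or without the mitochondrial limit, since a mutant library then held under 25 of its cells. The same held for proximal tubule with that centring, without the doublet step or without the mitochondrial limit, and for erythroid and immune cells with at least 1000 genes. Changes of 2-fold were mostly out of reach at this depth and number of libraries, as in the simulated counts.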

Other observations

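The tests in this part were chosen after the results were seen; the list sums over all barcodes use lists chosen before.

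Malat1, a nuclear RNA that is abundant in damaged or leaky cells, gave 2281 and 1673 CPM without TMM in the wildtype and 4508 and 6550 in the mutant libraries over all cells. Its log2 fold change was 1.36 (SE 0.42, adjusted p = 0.154 in edgeR), and in ureteric bud and collecting duct-like cells it was 1.85 (adjusted p = 0.0825). Over all barcodes, Xist stood at 0.713, 146, 729 and 409 CPM and the Y-linked gene Ddx3y at 96.6, 63.6, 1.12 and 77.1, in the order wildtype 1, wildtype 2, mutant 1 and mutant 2. Wildtype 1 thus had almost no Xist and mutant 1 almost no Ddx3y, so sex differed between the libraries of each genotype. The podocyte list summed over all barcodes to 2117 and 1664 CPM in the wildtype and 2925 and 3509 in the mutant libraries. The adrenal and gonad list summed to 2.95 and 2.05 against 12.3 and 3.98. In mutant 1 this came mostly from Gata4, Nr5a1 and Dhh (23, 7 and 6 UMIs). Mutant 2 had 9, 1 and 29 UMIs of them, and its Nr5a1 level (0.0468 CPM) lay below both wildtype libraries (0.204 and 0.242). The steroid-making genes Cyp11a1 (0.102 and 0.483 against 0.280 and 0.468) and Star (1.43 and 0.765 against 1.12 and 1.59) showed no clear rise. The stromal clusters tested separately called 24, 38, 113, 0 and 3 genes in clusters 2, 3, 4, 8 and 13. Cluster 20, left unnamed, held 64 cells, 25 of wildtype 1 and 39 of mutant 1, and none of the other libraries.

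Genes that differed the same way in every class. Of 2398 genes tested in all 10 classes, 43 separated the genotypes in every class. Grouping the libraries by replicate number instead gave 34 such genes, and the crossed grouping, wildtype 1 with mutant 2, gave 115. Differences between whole libraries that have nothing to do with genotype may therefore account for the 43.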
